A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

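Hi-C, which joins DNA ends that lie close together in fixed nuclei and counts the joined pairs by sequencing, was done on the budding yeast strain BY4742. Per the labels, cells grown at 25 °C were divided: 1 aliquot was fixed at 25 °C and the other was brought to 37 °C with prewarmed medium, kept there for 15 minutes and fixed at 37 °C, with 2 biological replicates of each. All were fixed in 3% formaldehyde and digested with HindIII. Because the heated aliquots were also fixed at 37 °C, and received fresh medium, these differences cannot be separated from that of temperature. Reads were aligned with Bowtie 1.1.0 to build R64, per the submitters' processing notes; the later steps and filters are not given in the sources used here.

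The deposited values are contact counts. The authors supplied 1 matrix per temperature in which the replicates are combined, with a whole number for each pair of restriction fragments and no names or coordinates for the fragments. The matrix of each temperature was recognised by its name alone. The 25 °C matrix held 4388 fragments and 5920062 contacts, and the 37 °C matrix held 4383 fragments and 1937970 contacts. Both were symmetric, with a diagonal sum of 0. There was therefore 1 map per group and no replicate error. No test between temperatures was run and no p-value is given. Intervals are exact 95% intervals for counts (Poisson for a ratio of observed to expected contacts, Clopper-Pearson binomial for a share or for a ratio between maps), and they cover counting error only. The spread over chromosomes is given as the range on leaving out each chromosome in turn.

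Chromosomes were recovered from the maps. A segmentation by contact counts split the 25 °C map into 16 blocks, the same from starting guesses in numeric and in alphabetical order. Block sizes in fragments followed the gene spans of chromosomes I to XVI in numeric order with a Pearson correlation across chromosomes of 0.993, against 0.685 in alphabetical order. The 37 °C map was aligned to the 25 °C map by the order and totals of fragments, which matched 4381 fragments and left 7 and 2 without a partner, none of them with more than 11 contacts. Segmented alone, the 37 °C map gave 30 blocks, and all 15 chromosome borders of the 25 °C map lay within 1 fragment of one of its borders. Centromeres were placed where inter-chromosomal contacts with the other centromeres peaked in the sum of the maps, starting from annotated positions; starting from the middle of each chromosome gave the same place, within 2 fragments, for 16 of 16. Their relative positions correlated with those in the RefSeq gene table of R64 at 0.990 across chromosomes, with a median distance of 16.0 kb and a largest of 40.7 kb, on chromosome VII. The rDNA was placed at the break in contacts of chromosome XII, 33.3 kb from its interpolated position. Fragments spanned 2.75 kb on average. Positions of genes were interpolated between these anchors, so each gene is known only approximately, and a gene result describes a neighbourhood of 11 fragments, about 30.3 kb. This reaches 5 fragments to each side, and the distances found at these landmarks can exceed that. The error in placing genes between the anchors was not measured, so a gene may lie outside its neighbourhood. Coordinates given with gene names are those of the gene table, not of the fragments counted.

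The lowest 2% of fragments by total contacts in either map were left out, which kept 4281 fragments. Expected inter-chromosomal contacts were the product of fragment factors fitted by iterative proportional fitting over inter-chromosomal pairs, so that each fragment's total was matched. Centromere regions reached 20 kb (7 fragments) to each side, chromosome ends 30 kb (11 fragments), and arm regions lay at least 100 fragments from the centromere and outside the ends. The arm regions, the classes by distance from the centromere, the comparison of arm lengths and the limit of 120 fragments within chromosome XII were chosen after seeing the data. Log2 ratios are the ratio at 37 °C over that at 25 °C. Pairs of neighbouring fragments were left out of intra-chromosomal contacts. A group of 580 fragments (13.5%) had a factor ratio between the maps above 2 times the median; they are called raised fragments, and results without them are an alternative chosen after seeing the data.

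Gene lists were fixed before the data were examined: Hsf1 targets, Msn2 and Msn4 targets, ribosomal protein genes, ribosome biogenesis genes, glycolytic genes, glucose-repressed genes, meiosis genes, tRNA genes, inducible genes described at the nuclear pore, and cell division genes. The ribosomal protein list was taken by a pattern of gene names, which also took in RPP1, a gene of RNase P. Each list was set against 10000 random lists matched on distance to the centromere, distance to the chromosome end and tercile of coverage. A contact inside overlapping neighbourhoods of a list is counted more than once, so the counting interval of a list is too narrow and the percentile is given beside it. Random genes were not matched on chromosome or on lying next to another member. The spread of random lists may therefore also be too narrow for lists with overlapping neighbourhoods, and extreme percentiles are to be read with that limit. The rule for named genes took, of chromosome pairs and of pairs of Hsf1 targets, the 3 highest and 3 lowest by log2 ratio with at least 20 contacts expected in each map, and chromosomes where highest or lowest. Its other part ranked genes by their share of short-range contacts: all Hsf1 targets led by the 5 highest and 5 lowest, the 3 highest and 3 lowest of each other list, and the extremes over all protein-coding genes. That share was not computed, because most short-range pairs are empty in both maps and genes could not be placed on single fragments; list members were ranked by contacts of each neighbourhood with the rest of its list instead, a choice made after seeing the data, and no ranking over all protein-coding genes was made. The lists for the strain check (HIS3, LEU2, LYS2 and URA3, absent from BY4742, and TRP1, ADE2, MET17, HIS4, LEU1, LYS1 and URA5, present) and for the mating loci (HMLALPHA1, HMLALPHA2, MATALPHA1, MATALPHA2, HMRA1 and HMRA2) need single fragments too and were not analysed here, nor was the planned test of separate replicates.

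The calculations used Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9. They were tested on simulated maps of the 37 °C against 25 °C comparison with 4281 fragments. A planted change of 0.8-fold (log2 -0.32) in contact rate between centromeres was returned as a mean log2 of -0.17 over 11 draws, close to the value of -0.17 without counting noise, which 10 of the 11 intervals covered. In this test the fitted factors absorbed part of the planted change. The effect on other classes of contacts was looked at with a separate planted change, given in the closing observations. A random list of 30 genes planted at 1.2-fold was returned at log2 0.20, at percentile 100 of 1000 random lists. Of 20 lists with no change, 1 lay outside the middle 95%. The list change was planted over the same whole neighbourhoods that were then read. Errors in placing genes were therefore not simulated, and a change at real genes may be recovered less well. Maps drawn at equal rates gave a chi-square per degree of freedom of 1.00, and 99.98% of 4372 aligned fragments were matched rightly. Alternatives covered the filter, the expectation, window sizes, depth, a cap of 5 contacts per pair and the regions used.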

Results

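Contacts between DNA fragments were counted in budding yeast grown at 25 °C and in yeast shifted from 25 °C to 37 °C for 15 minutes, a mild heat shock. Each temperature had 2 replicates, combined into 1 map, and fixation was done at the same temperature as the last growth. The 25 °C map held 5920062 contacts and the 37 °C map 1937970, with medians of 2729 and 718 contacts per fragment. Inter-chromosomal contacts numbered 5210385 and 1570770 after filtering. With 1 map per temperature there was no replicate check of any difference. The comparisons ask how the known arrangement of the yeast nucleus differed between these libraries.

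Centromeres of different chromosomes, which are held together at the spindle pole body in yeast, were the most enriched of the region classes in both maps, and less so at 37 °C. Regions within 20 kb of centromeres contacted each other at 5.10 times the expected rate at 25 °C (95% interval 5.07 to 5.13, 118663 contacts) and 4.45 times at 37 °C (4.39 to 4.50, 27274 contacts). The log2 ratio was -0.20 (-0.22 to -0.18), with a range of -0.22 to -0.16 on leaving out each chromosome. The ratio was lower at 37 °C for 16 of 16 chromosomes, with an interval below 0 for 15. Chromosome II had the highest ratio in both maps, 5.92 and 5.15, and chromosome VIII the lowest, 3.86 and 3.42. Over all fragments the difference was greatest for chromosome X, at 4.81 against 3.58 (log2 -0.42; -0.19 without raised fragments, as for chromosome VIII), and smallest for chromosome XV, at 5.11 against 5.00 (log2 -0.03, interval -0.09 to 0.02). Leaving out the raised fragments brought the log2 ratio to -0.11 (-0.13 to -0.09), with ratios of 5.14 and 4.76, and a cap of 5 contacts per pair brought it to -0.06. It was also -0.06 below the median factor ratio, -0.08 with a window of 10 kb, and -0.13 with each map's centromeres placed from the other map. The main placement used the sum of the maps, to which the 25 °C map gave more contacts, so it may favour the 25 °C ratio. Counts above the cap are more frequent in the deeper 25 °C map, so the cap acts unequally on the maps.

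**Figure D1:**
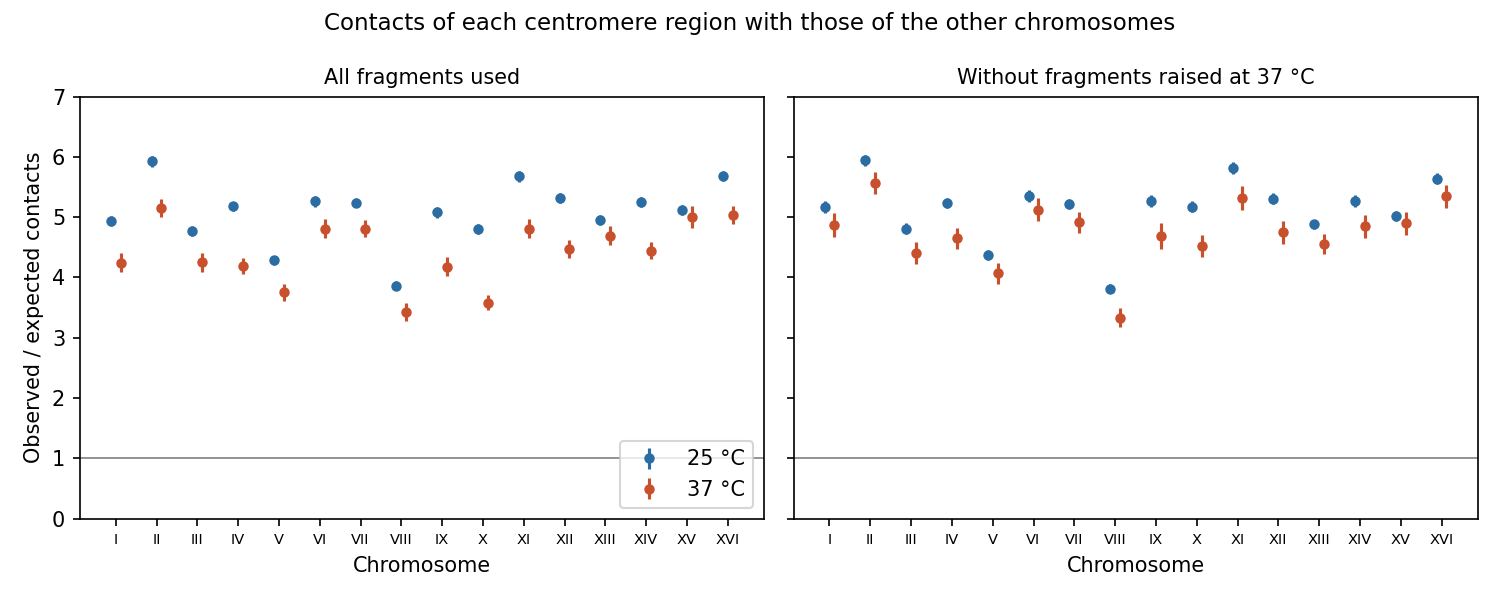
Observed over expected contacts of each centromere region with those of the other 15 chromosomes (vertical axis, no unit) for chromosomes I to XVI at 25 °C and 37 °C, with all fragments used (left) and without raised fragments (right); points are the ratios, bars are approximate 95% counting intervals, and the grey line marks 1. With all fragments, ratios run from 3.86 to 5.92 at 25 °C and from 3.42 to 5.15 at 37 °C.

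Contacts between centromere regions and chromosome arms lay below expectation in both maps, and less so at 37 °C. The expectation matches each fragment's total, so an excess between centromere regions lowers their ratios with other classes. The values below are therefore not independent of the centromere ratio. Centromere regions contacted arm regions on other chromosomes at 0.28 of the expected rate at 25 °C and 0.43 at 37 °C (log2 0.64, 0.62 to 0.66). Arm regions contacted each other at 1.40 and 1.30 times the expected rate (log2 -0.11, -0.11 to -0.10). The contrast grew with distance: between centromere regions and fragments 200 or more positions away, ratios were 0.23 and 0.41 (log2 0.83), while among those distant fragments they were 1.74 and 1.55 (log2 -0.16). Fragments 20 to 49 and 50 to 99 positions from the centromere contacted each other at 1.01 times the expected rate in both maps. Without the raised fragments, centromere and arm regions stood at 0.24 and 0.33 (log2 0.45). The log2 ratio between arm regions was then -0.06 (-0.07 to -0.05), and that among the distant fragments -0.06 (-0.09 to -0.03).

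**Figure D2:**
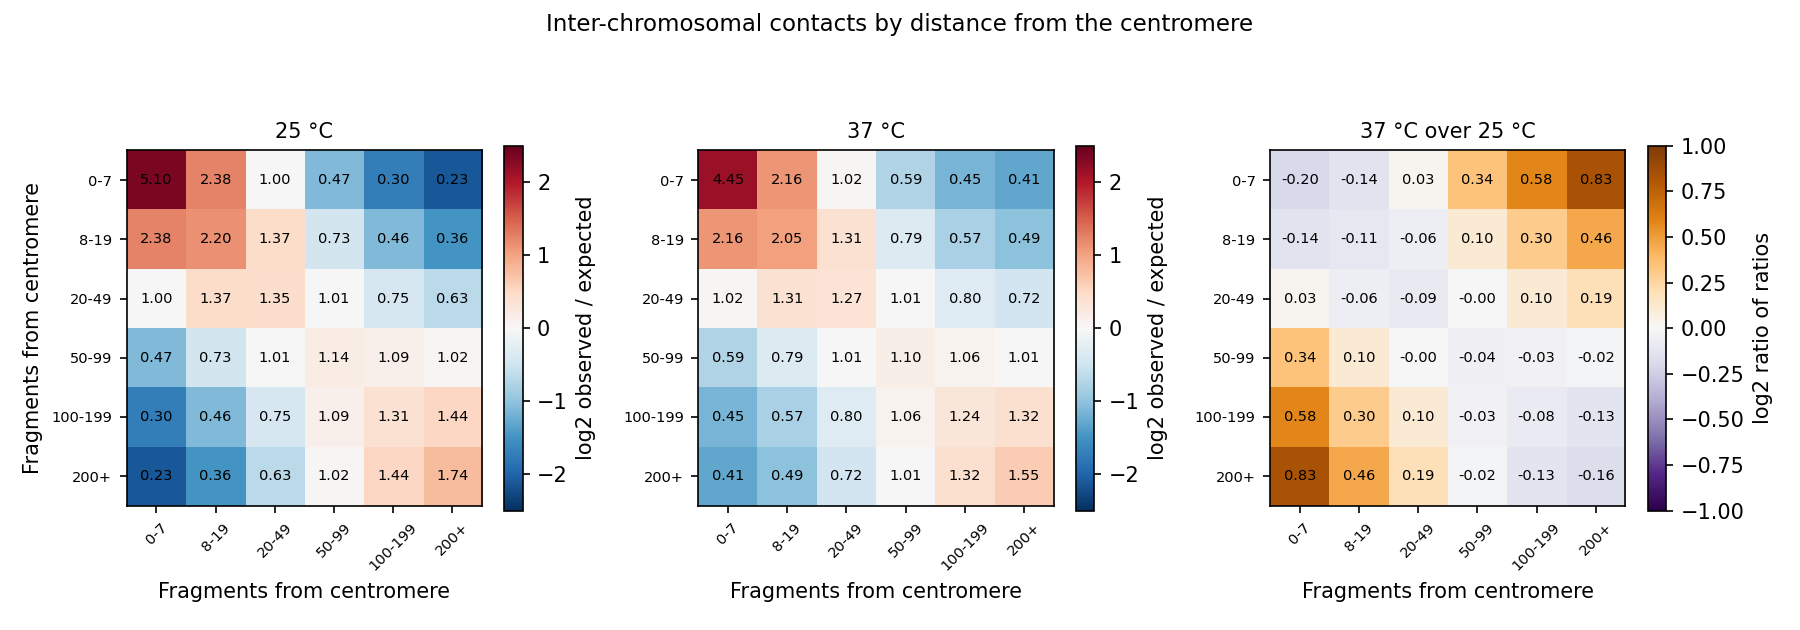
Inter-chromosomal contacts between classes of fragments by distance from their own centromere, in fragments (both axes), at 25 °C, at 37 °C and as the log2 ratio between them. Cell numbers are observed over expected contacts in the first panels and log2 ratios in the last; centromere regions fall from 5.10 to 4.45 with each other and the centromere to far-arm class stands at 0.23 and 0.41.

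Chromosome ends, which are anchored at the nuclear envelope, clustered with each other in both maps, with a lower ratio at 37 °C. Regions within 30 kb of ends on different chromosomes met at 2.01 times the expected rate at 25 °C (1.99 to 2.03) and 1.79 times at 37 °C (1.76 to 1.83), a log2 ratio of -0.16 (-0.19 to -0.13). All 32 arms had a ratio above 1 in both maps. It was lower at 37 °C for 29 of the 32 arms, with an interval below 0 for 16. Over all fragments the right arm of chromosome III had the highest ratio, 2.73 and 2.67, and the right arm of chromosome I the lowest in both, 1.28 at 25 °C. Without the raised fragments the ratios were 2.09 and 2.02 and the log2 ratio was -0.05 (-0.09 to -0.01), with 23 of 32 arms lower and 3 intervals below 0. Below the median factor ratio its interval included 0 (-0.13 to 0.02). Contacts between ends and arm regions were near expectation, at 1.01 and 1.02, and ends met centromere regions at 0.60 and 0.67 (log2 0.16). The last log2 ratio was 0.05 (0.00 to 0.09) without the raised fragments and 0.03 (-0.07 to 0.13) below the median factor ratio. With the cap of 5 contacts per pair it was 0.02 (-0.01 to 0.06), so no difference was called.

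Ends of arms of similar length had higher median ratios than ends of arms of different length, and short arms had high ratios as well, so similarity and shortness were not separated. Over 41 pairs of arms whose lengths differed by less than 25 fragments, the median ratio was 2.52 at 25 °C (quartiles 2.13 and 3.42) and 2.22 at 37 °C (1.68 and 3.28). Over 134 pairs differing by 100 fragments or more, the medians were 1.34 (1.06 and 1.86) and 1.21 (0.86 and 1.58). Over 27 pairs with both arms under 80 fragments they were 3.12 and 2.85, and some such ends lie close to the centromere. Over 43 pairs with both arms of 150 fragments or more they were 2.08 and 1.76. Without the raised fragments only 13 pairs of similar and 29 of different length kept enough expected contacts. Arms of similar length still had the higher medians, but theirs turned from lower to higher at 37 °C (2.50 and 2.93). The strongest pair at both temperatures joined the right arm of chromosome XIII with the left arm of chromosome XIV, at 6.12 and 5.36, whose lengths differed by 4 fragments. At 25 °C the left arm of chromosome III with the right arm of chromosome IX followed at 5.60, and the right arms of chromosomes I and IX at 5.24. At 37 °C the left arm of chromosome I with the right arm of chromosome XI came second, at 5.16, with lengths differing by 58 fragments. Without the raised fragments the highest pair at 25 °C was instead the right arm of chromosome III with the left arm of chromosome V, at 3.81 and differing by 22 fragments. At 37 °C it was the right arm of chromosome IV with that same arm, at 5.20, whose lengths differed by 337 fragments. These pairs were picked as the extremes after their values were seen. Each arm pair had at least 10 contacts expected in each map.

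The part of chromosome XII beyond the rDNA, the repeat array of the nucleolus, met the near part of its own chromosome at a low rate. That rate was below the rate of pairs the same number of mapped fragments apart on other chromosomes. In the gene table of R64 the annotated rDNA runs from 451575 to 489469 on chromosome XII. The part beyond it met centromere regions at 0.18 of the expected rate at 25 °C (0.18 to 0.19) and 0.35 at 37 °C (0.34 to 0.36), a log2 ratio of 0.95 (0.88 to 1.02). Without the raised fragments these ratios were 0.15 and 0.24 (log2 0.75). The part beyond the rDNA met arm regions of other chromosomes at 1.61 and 1.45 times the expected rate (log2 -0.15, -0.16 to -0.13, and -0.09 without raised fragments). It met chromosome ends at 0.87 and 0.92. Distant fragments of all chromosomes met centromere regions at 0.23 and 0.41, as given above, and no comparison between chromosomes was matched on that distance. Within chromosome XII, contacts across the rDNA were counted at separations of 120 fragments or more. They were 0.40 of those at the same separations in fragments on other chromosomes at 25 °C (0.39 to 0.41) and 0.39 at 37 °C (0.38 to 0.41). On the far side of the array alone this ratio was 3.29 and 2.03, and on the near side 2.35 and 2.01. The boundary had been placed at the break in contacts of these same maps. A low ratio across it and high ratios beside it were therefore partly built in, and the intervals do not cover that choice. Separations also count mapped fragments only, and the length of the array in these cells was not measured. Pairs across the array may lie farther apart than the pairs they were set against, so the ratio across it is not matched on DNA length. Without the raised fragments, the ratio across the rDNA was 0.39 at 25 °C and 0.32 at 37 °C (log2 -0.27). Most close pairs within chromosomes were empty, as given further on, which limits the intra-chromosomal values.

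Chromosomes I and VI, which are small, contacted each other most, with a lower ratio at 37 °C. Over the 120 chromosome pairs, the highest ratio in both maps was that of chromosomes I and VI, 2.27 and 1.99, and the lowest was that of chromosomes I and IV, 0.65 and 0.70. The 3 lowest log2 ratios were those of I and VI (-0.19), III and VI (-0.16) and VI and IX (-0.11). The 3 highest were those of IV and VI (0.15), I and IV (0.12) and VI and XIII (0.11). The log2 ratios had an SD of 0.05 over the pairs, against 0.02 in 200 simulations with counting noise alone. The interval lay below 0 for 15 pairs and above 0 for 21. Without the raised fragments it lay below 0 for 8 and above 0 for 7, and it included 0 for IV and VI (0.05, -0.01 to 0.11) and for VI and IX (-0.04, -0.11 to 0.03). I and VI stood at -0.13 and III and VI at -0.09, with III and IX between them (-0.10), and the highest was I and XIV (0.10).

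Neighbourhoods of the listed Hsf1 targets, most of them chaperone or co-chaperone genes, contacted each other as a set as often at 37 °C as at 25 °C within counting error. Between members on different chromosomes, observed over expected contacts of the 29 genes were 1.02 in both maps, and the log2 ratio was -0.00 (-0.04 to 0.03), at percentile 37.0 of matched random lists. The ratio itself stood at percentile 99.8 of random lists at 25 °C, whose median was 0.98, and at percentile 98.3 at 37 °C. The highest pairs at 25 °C were SSA1 with SIS1 (5.35, 588 contacts), SSA1 with HSP12 (4.07) and SSA1 with MDJ1 (3.88). SIS1 with HSP12 and with MDJ1 followed at 3.23 and 3.09. Of 207 pairs with enough expected contacts, only 92 lay above 1 at 25 °C and 94 at 37 °C. The list was not computed without its highest pairs, so these percentiles need not hold for the set as a whole. Without the raised fragments these percentiles were 99.7 and 76.9, and the log2 ratio was -0.04 (-0.08 to 0.01), at percentile 7.26. By neighbourhood, 13 members had a lower and 16 a higher ratio at 37 °C, with intervals below 0 for 4 and above 0 for 2. The lowest log2 ratios were those around HSP104 (-0.18; XII, 88623 to 91349), the disaggregase of aggregated proteins, TMA10 (-0.17), YDJ1 (-0.17), an Hsp40 co-chaperone, SSA2 (-0.15), a cytosolic Hsp70 whose neighbourhood overlaps that of HSP104, and HSC82 (-0.14), an Hsp90. The highest were those around SSA4 (0.18; V, 364589 to 366517), a heat-induced Hsp70, APJ1 (0.12), CUR1 (0.12), HSP60 (0.10), the mitochondrial chaperonin, and HSP10 (0.08), its cofactor. Between these lay CPR6, SSC1, SSA1, MBF1, HSP12, SSE1, MDJ1, HSP82, AHA1, STI1, HCH1, SIS1, SSA3, FES1, BTN2, HSP78, UBI4, HSP26 and HSP42, in rising order.

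Of 207 pairs of Hsf1 targets on different chromosomes with enough expected contacts, 92 had a lower and 115 a higher ratio at 37 °C. The interval lay below 0 for 17 pairs and above 0 for 26, and pairs that share a neighbourhood are not independent. The 3 lowest were SSC1 with TMA10 (34 contacts at 25 °C and 3 at 37 °C, log2 -2.07, -4.42 to -0.40), HSC82 with MBF1 (130 and 10, log2 -1.92) and SSC1 with YDJ1 (123 and 10, log2 -1.82). The 3 highest were HSP60 with SIS1 (1 and 9 contacts, log2 5.03, 2.17 to 10.5), MDJ1 with TMA10 (6 and 12, log2 2.53) and HSP12 with TMA10 (7 and 13, log2 2.24). MDJ1 and HSP12 are close neighbours on chromosome VI whose neighbourhoods overlap almost wholly, so the last 2 pairs are nearly 1 observation. SIS1 lies 10.1 kb from a centromere, and HSP60 and TMA10 lie on chromosome XII beyond the rDNA, so that the first of these pairs joins the regions that were most depleted of contacts at 25 °C.

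**Figure D3:**
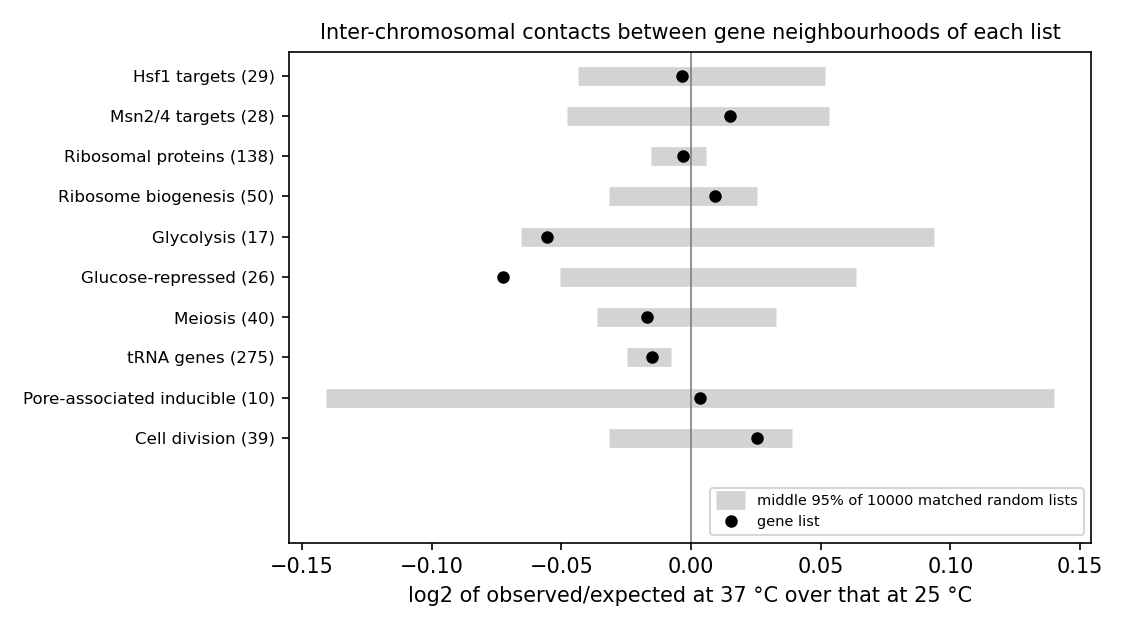
Log2 of observed over expected inter-chromosomal contacts at 37 °C over that at 25 °C (horizontal axis) for the 10 gene lists, with the number of genes in brackets; points are the lists and grey bars the middle 95% of 10000 matched random lists. The glucose-repressed genes, at -0.07, are the list outside its bar.

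Among the other lists, genes repressed in glucose had a lower ratio at 37 °C with neighbourhoods of 11 fragments, and the rest lay within the middle 95% of random lists. The 26 glucose-repressed genes stood at 1.04 at 25 °C and 0.99 at 37 °C, a log2 ratio of -0.07 at percentile 0.35, and 20 of the 26 neighbourhoods were lower. The lowest were those of the lactate transporter gene JEN1 (-0.30; XI, 22234 to 24084), POX1 (-0.26), of fatty acid oxidation, and ADH2 (-0.26), an alcohol dehydrogenase. The highest were those of ICL1 (0.20), of the glyoxylate cycle, CAT8 (0.15) and MLS1 (0.11; -0.16 without raised fragments). The list stood at -0.05 and percentile 7.43 without the raised fragments, at -0.02 (-0.10 to 0.06) and -0.01 (-0.03 to 0.01) with windows of 5 and 21 fragments, and at 0.06 below the median factor ratio. The lower ratio therefore does not hold across these choices, and with 10 lists compared a single extreme percentile is weak evidence.

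The 17 glycolytic genes had a log2 ratio of -0.06, at percentile 4.31, with 12 neighbourhoods lower, the lowest those of ENO2 (-0.26), GPM1 (-0.18) and FBA1 (-0.15) and the highest those of HXK2 (0.22), TDH2 (0.17) and PGK1 (0.14). Their log2 ratio was -0.11 without the raised fragments, at percentile 0.57, and -0.14 (-0.21 to -0.06) without members near centromeres and ends. It was -0.14 (-0.29 to 0.01) with windows of 5 fragments and 0.04 (0.01 to 0.08) with windows of 21. The sign of the value thus changed with the window, but these list intervals are too narrow and no percentile is given for the windows. The 138 genes of the ribosomal protein list, taken by name and including RPP1, of RNase P, contacted each other at 1.03 in both maps, at percentiles 99.6 and 99.9 of random lists, with a log2 ratio of -0.00 at percentile 62.8; the lowest were RPL6B (-0.13), RPL37B (-0.12) and RPL21A (-0.10) and the highest RPL14A (0.13), RPL14B (0.13) and RPS18B (0.10). The 50 ribosome biogenesis genes stood at 1.03 and 1.04, percentiles 95.3 and 99.1, with a log2 ratio of 0.01 at percentile 80.9, and of -0.02 (-0.03 to -0.01) with windows of 21 fragments, from NOG1 (-0.22), UTP20 (-0.16) and TIF6 (-0.16) to IMP4 (0.14), NOP7 (0.15) and SDA1 (0.17). The 28 targets of Msn2 and Msn4, the general stress regulators, had a log2 ratio of 0.01 at percentile 68.6, and of -0.09 (-0.17 to -0.01) with windows of 5 fragments, from NTH1 (-0.20), TSL1 (-0.13) and GLK1 (-0.10) to GPH1 (0.13), SOL4 (0.20) and GAC1 (0.24).

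The comparison lists lay among random lists in the main setting. The 40 meiosis genes had a log2 ratio of -0.02 (middle 95% of random lists -0.04 to 0.03), which was -0.05 (-0.08 to -0.02) without members near centromeres and ends and 0.03 (-0.03 to 0.08) with windows of 5 fragments, with REC102 (-0.21), SSP1 (-0.16) and SPO11 (-0.15) lowest and REC8 (0.24), SPO21 (0.16) and RED1 (0.15) highest. The 275 tRNA genes stood at -0.02, percentile 56.0; the lowest were YNCG0022W (-0.18) and YNCG0023C (-0.17), neighbours on chromosome VII, and EMT3 (-0.15), and the highest YNCG0030C (0.13), YNCG0029C (0.12) and YNCG0028W (0.12), also neighbours on chromosome VII. The 10 inducible genes described at the nuclear pore stood at 0.00, percentile 51.9, and at 0.07 (0.01 to 0.12) with windows of 21 fragments, from GAL1 (-0.18; 0.04 without raised fragments), INO1 (-0.18) and HXK1 (-0.10) to HIS4 (0.10), GAL2 (0.24) and ARG1 (0.26). The 39 cell division genes stood at 0.03, percentile 88.6, from CDC28 (-0.20), CLB4 (-0.18) and CDC27 (-0.13) to MCM4 (0.17), CDC24 (0.18) and CDC6 (0.22).

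Contacts within chromosomes were a minority in both maps, and most close pairs had none. Their share was 11.5% of contacts at 25 °C (11.4% to 11.5%) and 18.4% at 37 °C (18.4% to 18.5%), a difference of 6.99 percentage points. Over the alternatives this difference ran from 1.39 to 15.4 points. Pairs of fragments 2 to 3 positions apart were empty in 91.6% of cases at 25 °C, where counts of the same mean would leave 0.12% empty, and the other pairs had a median of 68 contacts. At 37 °C 86.3% were empty, against 9.41%, with a median of 13. Inter-chromosomal pairs showed no such gap, with 58.3% and 85.0% empty against 55.6% and 84.4% from the fitted factors. The slope of log10 contacts on log10 distance from 10 to 100 kb was -0.59 at 25 °C and -0.23 at 37 °C, with SDs of 0.32 and 0.17 over the 16 chromosomes, and from 100 to 500 kb it was -0.23 and -0.59. With so many empty pairs, the slopes are no measure of how contacts decay along the chromosomes.

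**Figure D4:**
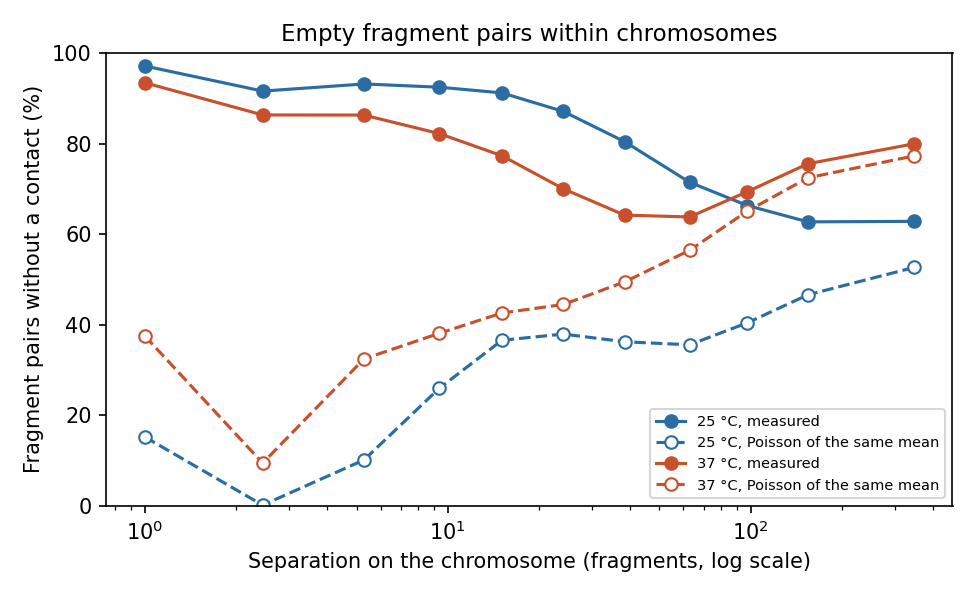
Share of fragment pairs within chromosomes that had no contact (vertical axis, percent) by their separation in fragments (horizontal axis, log scale) at 25 °C and 37 °C; filled points are measured shares and open points those of Poisson counts with the same mean. At 2 to 3 fragments the measured shares are 91.6% and 86.3% against 0.12% and 9.41%.

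The maps differed by more than counting noise. Over 31494 pairs of blocks of 50 kb, the chi-square per degree of freedom against equal rates was 9.67, and 20 simulations with equal rates gave a mean of 1.00 and a maximum of 1.02. Over inter-chromosomal blocks alone it was 4.81, and 2.26 once each map's own fragment factors set the expectation. These values compare the libraries, not the conditions.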

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

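No paired analysis was possible because both temperatures carry replicate numbers 1 and 2 but only maps of the combined replicates were used. Alternatives that leave out raised fragments, keep fragments below the median factor ratio, place centromeres from the other map, change the gene window, start at 120 fragments, or use each map's own factors or inter-chromosomal blocks alone were chosen after seeing the data; the others were set before the data were examined. The lower centromere and end ratios at 37 °C kept their direction in all 11 and 10 alternatives, with log2 ratios from -0.21 to -0.06 and from -0.20 to -0.05. Centromere values were -0.0635 with the cap of 5, -0.112 without raised fragments, -0.0644 below the median factor ratio, -0.0773 and -0.168 with windows of 10 and 40 kb, and -0.126 with centromeres placed from the other map. End values were -0.0513 and -0.0562 under both fragment restrictions, the latter with an interval of -0.13 to 0.02, and -0.203 and -0.128 with windows of 15 and 50 kb.

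Results within chromosomes depended on which pairs were counted. The difference in slope, 0.36, reversed to -0.085 from 20 to 200 kb and to -0.146 from 120 fragments on. The difference in intra-chromosomal share was 10.5 and 15.4 points under both fragment restrictions, 6.85 without pairs under 20 kb, 7.44 without chromosome XII and 1.39 from 120 fragments on. The log2 ratio across the rDNA was -0.271 and -0.211 under the fragment restrictions and 1.24 with 100 kb on each side, where most pairs were empty. The SD over chromosome pairs was 0.0721 without centromere and end regions. The chi-square per degree of freedom was 2.26 with each map's own factors, 4.81 between chromosomes, 3.58 and 23.8 with blocks of 20 and 100 kb, 5.80 after thinning, and 7.62 and 4.48 under the fragment restrictions. The Hsf1 targets stood at log2 0.031 with windows of 5 fragments. Over the 10 lists, 88 of 110 alternative values lay within the counting interval of the main value, 21 moved, and that of the glucose-repressed genes reversed to 0.0595 below the median factor ratio. Among lists whose main interval included 0, signs changed too. Glycolytic genes stood at 0.04 and ribosome biogenesis genes at -0.02 with windows of 21 fragments. Msn2 and Msn4 targets stood at -0.09 with windows of 5, and ribosomal protein genes at 0.02 below the median factor ratio. Their counting intervals excluded 0, but those of lists are too narrow, and no percentile is given for these alternatives. For all of these, above and here, the cause was not tested. The gene body with 2 kb on each side, the alternatives for short-range shares and those for separate replicates were not run. The 37 °C map had the fewer contacts in total.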

Other observations

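Tests on background between raised fragments, on leaving them out, on a uniform background, on planted clustering, on a planted centromere change and on empty pairs were chosen after the results were seen; those on neighbours, on chromosome ends and on depth were set before their values were computed. The ends of a chromosome also met each other, a comparison chosen after seeing the data. On chromosome III, whose ends carry the silent mating type loci, regions within 30 kb of the opposite ends had 456 contacts at 25 °C, 11.4 times the inter-chromosomal expectation (10.4 to 12.5), and 95 at 37 °C, 9.54 times (7.72 to 11.7). This was the highest ratio of the 16 chromosomes in both maps, but without the raised fragments it was 12.8 and 14.6, so the direction between maps was not settled. Chromosomes I and VI, also short, followed at 7.16 and 6.07 at 25 °C and at 7.37 and 5.81 at 37 °C. The ends of chromosome XII, which lie on either side of the rDNA, stood at 0.63 (0.45 to 0.86) at 25 °C and at 1.19 (0.73 to 1.84) at 37 °C. Both were the lowest of the 16 with all fragments. Without the raised fragments chromosome IV was lower at 37 °C, at 1.13 against 1.36.

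The 580 raised fragments took 13.1% of inter-chromosomal contact ends at 25 °C and 28.7% at 37 °C, and contacted each other at 1.76 and 1.44 times expectation. Spatial clustering of their loci stays open: neighbours within 3 positions contacted each other at 0.962 and 0.871 of the ratio of fragments 10 to 20 positions away, but clustering of that strength among these neighbours, when planted, was fitted at only 0.93 and 1.02. Raised fragments were not more frequent near chromosome ends: their share among the 297 fragments used there was 0.967 of that elsewhere. The 100 fragments left out for few contacts, many of them near ends, could not count as raised. Repeats near ends therefore cannot be judged from this share. Raised fragments near centromeres met raised fragments far from them at 1.37 times expectation at 25 °C and 1.14 at 37 °C, against 0.25 and 0.36 among other fragments. A candidate explanation is ligation without spatial order between these fragments; what sets them apart in sequence or length was not analysed here.

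Fewer counts alone did not produce the lower centromere ratio at 37 °C, since even thinning of the 25 °C map left the log2 ratio at -0.194. Such thinning lowers observed and expected contacts together, so it cannot speak to other effects linked to depth. Without the raised fragments, -0.112 (-0.13 to -0.09) remained, and with only fragments below the median factor ratio -0.064 (-0.11 to -0.02). The difference thus shrank as the limit on the factor ratio was tightened. The cut of 2 times the median divides a continuous ratio, so leaving out raised fragments cannot exclude the same effect in fragments below the cut. A uniform background of contacts at 37 °C stays open: in 16 of 16 classes by distance from the centromere that lay away from 1 at 25 °C, the ratio lay nearer to 1 at 37 °C, by 21.5% in the median and by 13.0% to 28.2% (median 11.9% without raised fragments). These classes share fragment totals and are not independent. An equal fall planted between centromere regions alone moved only 10 of the 16 nearer to 1. Over the 16 the shift towards 1 then had a median of 1.87% and ran from -17.2% to 16.0%, so its upper end overlapped the measured range. A real loosening of the arrangement in heated cells, or an effect of fixing at 37 °C, could give the same values, and the share of contacts within chromosomes, which such a background would lower, cannot be read because of the empty pairs.

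The empty pairs within chromosomes were not explained by poor coverage of the fragments. Empty pairs at 2 to 3 positions exceeded those of Poisson counts that follow each fragment's coverage by at least 61.5 percentage points in both maps. Across chromosome borders 8 of 22 such pairs were empty at 25 °C, 36.4% (17.2% to 59.3%), and 14 of 22 at 37 °C, 63.6% (40.7% to 82.8%), which lies 22.7 percentage points below the 86.3% within chromosomes. Against Poisson counts of equal mean, empty pairs within chromosomes were in excess by at least 76.9 percentage points. A candidate explanation is a filter applied to intra-chromosomal pairs before deposit, which kept pairs with many contacts; no biological explanation was tested.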
